A study of Mus musculus with 2 samples.

How the data were processed

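Ribosomal RNA-depleted total RNA over 200 nt from hindbrain of mice at postnatal day 0 (strain B6NTac;B6NCrl/Lap, both sexes pooled) was sequenced as stranded pairs of 101 nt, per the labels. The series holds 2 libraries of 1 group, replicates 1 and 2, numbered as in the labels. The labels call them independent isolates of the tissue and give 15 mice for replicate 1, while the number for replicate 2 is not given. Both carry a single donor identifier, so the spread between them may be technical in part.

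For each library the authors deposited a table per gene and a table per transcript. Per the deposited file notes they were made from alignments to the transcriptome with genome build mm10 and GENCODE release M4, and the aligner, the quantifier and their versions are not given in the sources used here. Per the file headers the deposited expected counts are estimated fragment counts that need not be whole, since reads that fit several transcripts are divided among them. Among values over 0, 7.9% (replicate 1) and 8.5% (replicate 2) lay over 0.005 from a whole number. The deposited TPM values divide counts by effective length and have a fixed sum over all rows, spike-ins included, and the deposited FPKM values are a constant multiple of TPM in each library. The deposited percent columns give each transcript's share of its gene's TPM. Posterior mean values and interval bounds are also deposited, and the level of the interval is not stated in the files. Whether the counting used strand is not stated, so values of genes that overlap others on the opposite strand are uncertain.

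Each gene table held 69691 rows, of which 43346 were Ensembl genes, 26248 were named by a number and had no counts, 96 were ERCC spike-ins and 1 was phiX. GENCODE release M21, annotated on the same genome build, supplied symbols, gene types and coordinates by Ensembl identifier, with 42462 genes (98.0%) matched. Unmatched genes held 0.131% and 0.150% of the counts and stayed in library sizes. Rows that name no mouse gene stayed out of library sizes and ratios. Ahsp, Rmst and Snhg1 from the gene lists and Mirlet7bhg from the pairs found no match, and Lin28b was therefore not compared.

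Totals were 54313140 and 77142270 expected counts (53617723 and 76299141 on mouse genes). Mean fragment lengths, taken from the difference of length and effective length, were 314.9 and 296.6 nt. A count of 0 was set against a floor of 3 counts, converted to TPM with the gene's effective length in each library. Reads carry no molecular identifiers, so such floors and simulated counting errors cover counting error only. They leave out how shared reads were assigned, and for some genes at 0 the upper bound of the deposited interval is higher, as for Dlx6 (0.586 TPM in replicate 1 against 0.049). The chi-square between the libraries over genes was 100.7 per degree of freedom against counting error, which rules out a repeat run of 1 library but not 2 preparations of 1 RNA sample. They were counted as 2 samples because the labels name them so.

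Gene lists, gene pairs, isoform genes, the main comparisons and the rule for named genes were set before the data were examined. The tests of explanations in the closing section, and the settings named as such below, were chosen after. There were 32 lists of cell types, tissues and functions, 15 pairs and 25 isoform genes. The text names up to 4 of the highest and up to 2 of the lowest members of each list, the 12 highest coding and 8 highest non-coding genes, the 10 coding genes with the largest ratio in each direction at a mean count of at least 200, pair and isoform genes and Hox genes. Some members that this rule covers are withheld and are not reported here. Other members appear where a list is described, chosen after their values were seen. A gene was detected at a TPM of at least 1 in both libraries. A list's level was the median of log2(mean TPM + 0.1), given as a percentile among 10000 random lists of equal size from 21461 protein-coding genes, for 29 lists of nuclear genes. The imprinted list was compared with the same coding pool although it includes the non-coding Meg3.

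Ratios between libraries used expected counts rounded to whole numbers, TMM scaling in edgeR 4.0.16 (R 4.3.3) and log2 scaled counts with a prior count of 2. The coefficient of variation came from edgeR with an intercept-only design and genes with a mean count of at least 10. A list's shift was the median log2 ratio of members with a mean count of at least 10, as a percentile among 10000 random lists drawn with replacement within 20 bins of mean count. That minimum, the percentile limits of 2.5 and 97.5 used to count lists the 50% limit for transcript shares and the comparison of spread with spike-ins were chosen after the data were seen. Lists share some genes (Otx2, Egr2, Slc2a1, Igf2, Xist and Meg3 are each in 2), so they are not independent. DESeq2 1.42.0 size factors, total counts and spike-in totals were alternative scalings. TMM, DESeq2 and total counts differed by under 0.001 in log2, and the spike-in total raised the median ratio of coding genes to 0.09.

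The steps were tested on simulated data. With the means and depths of these libraries, 4 groups of 50 genes changed by log2 values of −2, −1, 1 and 2 were recovered with medians of −2.00, −0.99, 0.99 and 2.01 under counting error alone, and coefficients of variation of 0.05, 0.15 and 0.3 over 17632 genes were recovered as 0.050, 0.148 and 0.298. For the list shift, 4.5% of 400 random lists of 15 genes fell outside the central 95% with no planted shift, 88.0% with a shift of 0.3 and 100% with a shift of 1. The rate with no planted shift follows from drawing lists at random, so it checks the calculation only. It does not cover lists of genes that move together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.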

Results

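Total RNA of hindbrain from newborn mice (postnatal day 0) was sequenced in 2 libraries, which form the single group of the series. The hindbrain holds the cerebellum, pons and medulla. Each library came from a pool of animals of both sexes, with 15 mice in replicate 1 and a pool of unstated size in replicate 2. Ribosomal RNA had been depleted, RNA over 200 nt was kept and synthetic spike-in RNA was added. The deposited tables held 54313140 expected counts for replicate 1 and 77142270 for replicate 2, and 18813 and 19535 annotated genes had at least a fraction of a count. With no second condition, the comparisons are between genes within the tissue and between the 2 libraries. Transcript levels are given in TPM as mean ± SD (n = 2). An exact sign-flip test over 2 libraries cannot go below p = 0.5, so no p-values are given.

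The most abundant nuclear messenger RNAs of the newborn hindbrain encoded cytoskeletal proteins, histones and housekeeping proteins. Tuba1a, the main α-tubulin of growing neurons, led with 5140 ± 1287 TPM (SD, n = 2). The β-tubulin genes Tubb2a, Tubb2b and Tubb3 had 1554 ± 416, 1300 ± 427 and 910 ± 260 TPM. The imprinted gene Nnat had 2217 ± 912 TPM, the mitochondrial ATP synthase gene Atp5b 1576 ± 438, the actin gene Actb 1317 ± 389, the elongation factor gene Eef1a1 1309 ± 326 and the chaperone gene Hspa8 906 ± 229. The histone H4 genes Hist1h4d, Hist1h4c and Hist1h4n completed the 12 highest, at 4135 ± 745, 1700 ± 410 and 1082 ± 263 TPM. In all, 11725 of 21461 protein-coding genes reached 1 TPM in both libraries. Protein-coding genes of the nuclear genome took 82.4 ± 1.44% of the expected counts and mitochondrial genes 11.1 ± 0.689%.

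By TPM, 5 structured non-coding RNAs exceeded every messenger RNA. Rn7sk, which regulates transcription elongation (chromosome 9, 78175303 to 78175633, mm10), had 266199 ± 141594 TPM (SD, n = 2). The signal recognition particle genes Rn7s1 and Rn7s2 had 123985 ± 3080 TPM each, with the same values in each table, so reads from these near-identical copies were split between them and their separate levels are uncertain. Rmrp and Rpph1, the RNA parts of ribonucleases MRP and P, had 100803 ± 74147 and 63565 ± 25183 TPM. Together the 5 genes held 61.7% of TPM in replicate 1 and 74.0% in replicate 2, but 1.17% and 4.34% of the counts. Their length of at most 331 nt is close to the mean fragment length of 314.9 and 296.6 nt, so the effective length by which counts were divided was 2.93 nt for Rmrp and 24.9 nt for Rn7sk in replicate 1. The next non-coding genes were the mitochondrial ribosomal RNAs mt-Rnr2 (37812 ± 13715 TPM) and mt-Rnr1 (7264 ± 752) and the long non-coding Gm26917 (2351 ± 744). Because TPM has a fixed sum, the TPM of a typical coding gene was 1.42-fold lower in replicate 2 although the median log2 ratio of its scaled counts was −0.01. The SD of every TPM includes this shared factor. It makes the SD too small where scaled counts were higher in replicate 2. Slc17a7 (2.505 ± 0.007 TPM) and Mbp (36.8 ± 0.544) had log2 count ratios of 0.52 and 0.48, so a small SD need not mean close agreement.

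Hox genes of paralogue groups 2 to 8 were expressed, those of groups 9 to 13 were at or near 0, and most forebrain transcription factors were low. Hoxa5 (chromosome 6, 52201754 to 52204587, mm10) was the highest Hox gene with 24.1 ± 4.97 TPM (SD, n = 2), followed by Hoxb8 (chromosome 11, 96281905 to 96285315) with 11.96 ± 9.32. Of the 15 anterior Hox genes (groups 1 to 5), which pattern the hindbrain along its axis, 11 reached 1 TPM in both libraries. Hoxb3 had 9.94 ± 2.62, Hoxb2 8.47 ± 2.38, Hoxd3 7.89 ± 1.20, Hoxa2 5.43 ± 2.29, Hoxb5 4.63 ± 0.035, Hoxd4 3.69 ± 0.290 and Hoxc4 3.00 ± 0.700 TPM. Hoxa3 had 2.15 ± 0.382, Hoxc5 1.73 ± 0.962, Hoxb4 1.41 ± 0.339 and Hoxa4 1.47 ± 0.778 TPM, the last with 0.92 TPM in replicate 2, while Hoxd1 and Hoxb1 had 0.260 ± 0.297 and 0.020 ± 0.028.

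Of the 24 posterior Hox genes (groups 6 to 13), which mark spinal cord and trunk, Hoxb8, Hoxb6, Hoxa6 and Hoxb7 reached 1 TPM in both libraries. Hoxb6 had 6.44 ± 2.81, Hoxa6 4.78 ± 3.42 and Hoxb7 4.08 ± 2.79 TPM (SD, n = 2). Hoxd8 had 2.55 TPM in replicate 1 and 0.07 in replicate 2. Hoxa7, Hoxc6, Hoxb9, Hoxa9, Hoxc8 and Hoxd13 lay between 0.020 and 0.660 TPM on average. The other 13, Hoxa10, Hoxa11, Hoxa13, Hoxb13, Hoxc9, Hoxc10, Hoxc11, Hoxc12, Hoxc13, Hoxd9, Hoxd10, Hoxd11 and Hoxd12, had 0 counts in both libraries, where 3 counts would be 0.051 TPM or less.

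Of the 18 forebrain genes, Bcl11b, Lhx2 and Neurod6 reached 1 TPM in both libraries, with 7.29 ± 2.16, 6.77 ± 3.54 and 5.39 ± 1.96 TPM (SD, n = 2). Dlx1 had 0.680 ± 0.028 TPM. Dlx5, Dlx6 and Rax had 0 counts, where 3 counts would be 0.049 TPM or less. The median log2 level of the anterior Hox genes exceeded that of the forebrain genes by 3.20 in replicate 1 and 3.74 in replicate 2, a mean of 3.47 ± 0.377 on the log2(TPM + 0.1) scale and over 3 SD. The size depends on the pseudocount, since it was 4.06 with 0.01 and 1.74 with 1. Midbrain and isthmus genes were measured at 8 of 12 over 1 TPM, led by Pax8 (9.25 ± 4.43), Otx2 (8.41 ± 0.990), En2 (8.13 ± 2.34) and Gbx2 (5.98 ± 2.46). Fgf17 and Wnt1 had 0.065 ± 0.092 and 0.005 ± 0.007.

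**Figure D1:**
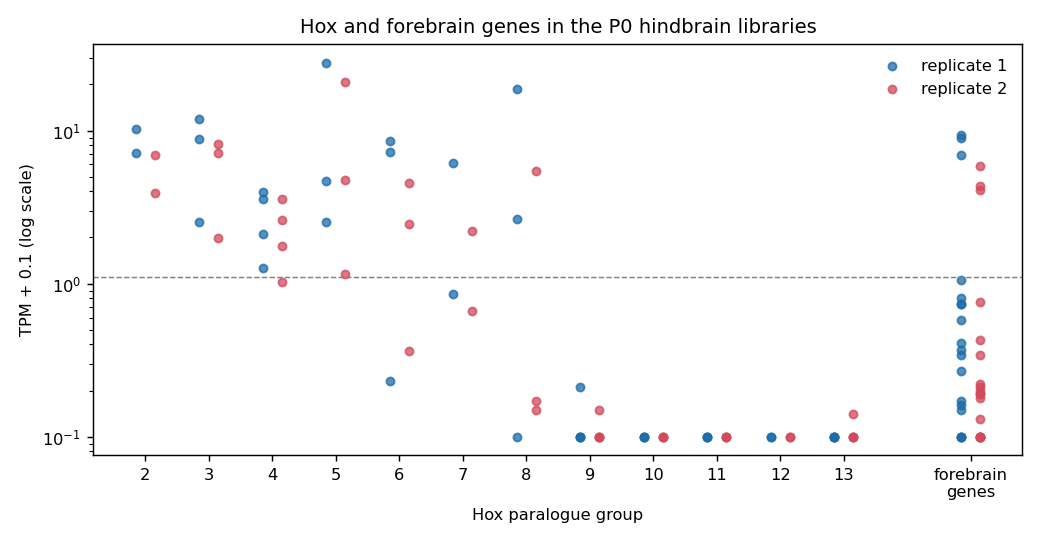
TPM plus 0.1 (log axis) of each Hox gene of paralogue groups 2 to 13, and of the forebrain transcription factors, with a point for each gene and library and a dashed line at a TPM of 1. Groups 2 to 8 hold genes over the line, with Hoxa5 highest at 27.7 and 20.6 TPM, and groups 9 to 13 hold none.

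Both cerebellar lineages were well represented. In the granule cell lineage 23 of 25 genes reached 1 TPM in both libraries, led by the zinc finger genes Zic1 (71.9 ± 9.31 TPM, SD, n = 2) and Zic2 (55.0 ± 14.4), Meis2 (31.2 ± 8.37) and Zic4 (28.8 ± 1.61). Atoh1, the transcription factor of granule cell progenitors, had 3.88 ± 0.969. Markers of mature granule cells were the lowest, with Cbln3 at 0.885 ± 0.700 and the GABA-A receptor gene Gabra6 at 0 counts, where 3 counts would be 0.020 TPM or less. Of 16 Purkinje cell genes 15 reached 1 TPM, led by Pcp4 (50.5 ± 12.7), Cbln1 (40.05 ± 8.68), Pcp2 (27.1 ± 0.849) and Calb1 (16.5 ± 5.34). Shh, which Purkinje cells release, was lowest at 0.920 ± 0.071. The median level of both lists lay above that of most random lists of protein-coding genes of the same size, at the 99.9th and 99.7th percentile of 10000 such lists, which describes these libraries and is not a test across animals. Many coding genes in that pool were not expressed, and against genes with a mean TPM of at least 0.1, given in brackets below, the 2 lists lay at the 97.3rd and 95.04th. Only the random pool was filtered in this way. List members at or near 0 stayed in, so every percentile given among expressed genes could only fall.

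Genes common to neurons were the highest of the cell type lists. All 18 reached 1 TPM, and after Tubb3 came the microtubule gene Map2 (257 ± 65.9 TPM, SD, n = 2), the neurofilament gene Nefl (189 ± 56.1) and the growth cone gene Gap43 (132 ± 47.2), with Rbfox3 (12.02 ± 2.75) and Camk2a (2.06 ± 0.382) lowest. All 9 glutamate neuron genes reached 1 TPM. Grin1 (35.4 ± 7.81), Gria2 (30.8 ± 7.98) and Slc17a6 (25.2 ± 8.04) were among the highest, and Slc17a7 (2.505 ± 0.007) and Slc17a8 (1.27 ± 0.106) lowest. All 10 GABA and glycine genes did so too, with Slc6a9 (27.6 ± 3.11), Gad1 (25.9 ± 7.99) and Glrb (21.5 ± 3.39) among the highest, down to Gad2 (8.93 ± 3.20) and Glra1 (3.30 ± 1.499). These 3 lists lay at the 100th, 99.9th and 99.8th percentile of random lists (100th, 99.5th and 98.9th among expressed genes).

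Genes of the smaller brainstem nuclei were lower. Among 11 serotonin neuron genes 7 reached 1 TPM, with the serotonin transporter Slc6a4 at 6.19 ± 2.29 TPM (SD, n = 2), Lmx1b at 4.60 ± 1.82, Ddc at 2.90 ± 0.382 and Slc18a2 at 2.81 ± 0.354. Slc22a3 and Fev, the lowest, had 0.570 ± 0.226 and 0.170 ± 0.198. The 7 genes listed for noradrenaline neurons and Phox2 factors, Calca among them, need not mark these neurons alone. Of these 5 reached 1 TPM, with Calca (4.51 ± 0.615), Dbh (3.53 ± 0.523) and Th (3.09 ± 1.12) among the highest, with Phox2a at 0.915 ± 0.304 and Gal at 0.285 ± 0.276. Of 11 cholinergic and motor neuron genes 5 did, led by Prph (14.7 ± 6.56), Ret (10.4 ± 4.02), Slc18a3 (7.43 ± 2.18) and Isl1 (4.65 ± 2.01), with Isl2 (0.335 ± 0.148) and Mnx1 (0.015 ± 0.021) lowest. The medians of these lists lay at the 51.4th, 61.4th and 36.9th percentile of random lists, but at the 6.76th, 20.9th and 1.43rd among expressed genes.

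Glial genes were mostly detected, and myelin genes ranged from high to absent. All 19 radial glia and astrocyte genes reached 1 TPM, led by Apoe (527 ± 72.4 TPM, SD, n = 2), Vim (239 ± 76.9), Aldoc (190 ± 46.2) and Fabp7 (172 ± 52.1), with Sox9 (3.45 ± 1.71) and Hes1 (3.18 ± 0.877) lowest. All 9 oligodendrocyte precursor genes did so, with Olig1 at 57.4 ± 13.7, Olig2 at 15.5 ± 5.38, Pdgfra at 13.3 ± 4.05 and Gpr17 at 11.4 ± 0.679, and Nkx2-2 (6.40 ± 2.01) among the lowest. Of 12 myelin genes 9 reached 1 TPM. Mbp had 36.8 ± 0.544, Cnp 25.2 ± 1.93 and Cldn11 16.3 ± 1.35, whereas Mog, a late myelin protein, had 24 counts in replicate 2 and none in replicate 1, and Opalin had 0 counts in both (3 counts would be 0.024 TPM or less). The radial glia list lay at the 100th percentile of random lists, the precursor list at the 94.2nd and the myelin list at the 55.7th (100th, 77.7th and 6.10th among expressed genes).

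Microglial, vascular and meningeal genes were present, and genes of tissue outside the brain were mostly low. Of 14 microglia genes 10 reached 1 TPM, led by C1qc (18.6 ± 1.97 TPM, SD, n = 2), with Ptprc (0.395 ± 0.233) and Aif1 (0.355 ± 0.445) lowest. All 12 endothelial genes did, led by the tight junction gene Cldn5 (44.9 ± 14.3) and the glucose transporter gene Slc2a1 (36.0 ± 9.77), with Tek (1.82 ± 0.728) and Slco1a4 (1.25 ± 0.318) lowest. Of 9 pericyte and smooth muscle genes 6 did, led by Vtn (31.8 ± 15.3) and Rgs5 (10.3 ± 3.63), with Anpep (1.04 ± 0.714) and Myh11 (0.140 ± 0.042) lowest. Of 12 meningeal and fibroblast genes 11 did, led by Ptgds (451 ± 38.3) and Igf2 (66.0 ± 10.03), with Foxd1 lowest (0.855 ± 0.587). Of 14 choroid plexus and ependyma genes 11 did, led by the thyroxine carrier Ttr (325 ± 14.8) and Enpp2 (17.1 ± 2.27), with Ccdc153 lowest (0.065 ± 0.064). The medians of these lists lay at the 65.7th, 84.2nd, 53.4th, 99.1st and 56.4th percentile of random lists, but at the 11.3rd, 41.9th, 9.68th, 92.2nd and 5.69th among expressed genes.

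Red blood cell RNA was dominated by adult globins. Hba-a2 had 437 ± 73.8 TPM (SD, n = 2), Hbb-bs 232 ± 27.2, Hba-a1 170 ± 27.7 and Hbb-bt 51.5 ± 13.04, and the split within the α and the β pair is uncertain because these near-identical genes share reads. The embryonic globins Hbb-bh1 and Hbb-y and the gene Hemgn had 0 counts (3 counts would be 0.122 TPM or less), and 5 of 11 measured erythroid genes reached 1 TPM. Of 15 cartilage, bone and muscle genes Col2a1 (5.86 ± 3.08) and Acta1 (20.005 ± 22.7) reached 1 TPM in both libraries, and Bglap had 0 counts (3 counts would be 0.440 TPM or less). Of 8 Schwann cell genes Pmp22 (13.5 ± 1.00) and Foxd3 (1.64 ± 0.884) did, with Cdh19 and Gldn at 0.255 ± 0.064 and 0.255 ± 0.304. Of 11 inner ear and pituitary genes Myo7a (10.5 ± 1.47) and Pomc (1.11 ± 0.092) did, and the hormone genes Gh, Prl, Tshb and Cga and the pituitary factor Pou1f1 had 0 counts (3 counts would be 0.127 TPM or less). These 4 lists lay at the 9.38th, 20.5th, 27.1st and 1.26th percentile of random lists, and all at or below the 0.3rd among expressed genes.

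Genes of dividing cells were all detected, and replication-dependent histone genes were among the highest of any list. All 20 cell division genes reached 1 TPM, led by Pcna (36.2 ± 3.99 TPM, SD, n = 2), Mcm6 (16.5 ± 7.20), Top2a (10.3 ± 2.63) and Cdc20 (9.22 ± 2.02), with Birc5 (2.17 ± 0.884) and Bub1 (1.63 ± 0.163) lowest. All 26 histone genes, whose messenger RNA has no poly(A) tail, did so. After Hist1h4d and Hist1h4c the highest were Hist1h3a (551 ± 222) and Hist2h3b (468 ± 232), and the lowest were Hist1h1a (11.4 ± 3.56) and Hist1h4i (6.63 ± 1.27). The division list lay at the 89.0th percentile but at the 37.9th among expressed genes, and the histone list at the 100th in both. Both percentiles rest on TPM, which is high for short genes relative to counts. Hist1h4d had an effective length of 79.6 nt in replicate 1 and a mean of 44332 counts against 228552 for Actb. Many of the histone genes are near-identical copies with counts that were not whole, so their separate levels are uncertain.

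Imprinted genes also lay at the 100th percentile in both, with 18 of 20 over 1 TPM in both libraries. Below Nnat, Meg3 had 234 ± 14.05 TPM (SD, n = 2), Ndn 210 ± 62.9 and Mest 184 ± 106, while Zrsr1 (1.53 ± 0.933) and Rtl1 (0.375 ± 0.021) were lowest. Of 12 hypoxia and glycolysis genes 10 did, led by Ldha (103 ± 19.6), Pgk1 (56.5 ± 15.1), Slc2a1 and Bnip3 (32.3 ± 0.283), with Adm (0.505 ± 0.148) and Car9 (0.035 ± 0.021) lowest, at the 98.9th percentile (90.7th among expressed genes). Of 15 immediate early genes 9 did, led by Jun (19.2 ± 6.97), Dusp1 (11.97 ± 2.99), Fos (5.13 ± 0.926) and Junb (3.97 ± 0.898), with Fosb (0.050 ± 0.042) and Egr4 (0.035 ± 0.049) lowest, at the 44.2nd percentile (1.94th among expressed genes). Among other non-coding RNA, Rian had 660 ± 158 and Malat1 332 ± 78.8, with Kcnq1ot1 (0.840 ± 0.028) and Neat1 (0.715 ± 0.177) lowest. Of the 13 messenger RNAs of mitochondrial DNA mt-Co1 was highest (5048 ± 1065), followed by mt-Co3 (2992 ± 844), mt-Nd4l (1125 ± 48.4) and mt-Co2 (932 ± 185). mt-Nd6 was low (174 ± 53.0), and mt-Atp8 was listed at 0 TPM with 53 and 199 counts because its effective length was 0. Xist, the RNA of the inactive X, had 14.4 ± 7.43 TPM, and the Y genes Eif2s3y, Uty, Ddx3y and Kdm5d had 4.53 ± 0.919, 2.62 ± 0.721, 2.54 ± 0.226 and 2.13 ± 0.354.

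**Figure D2:**
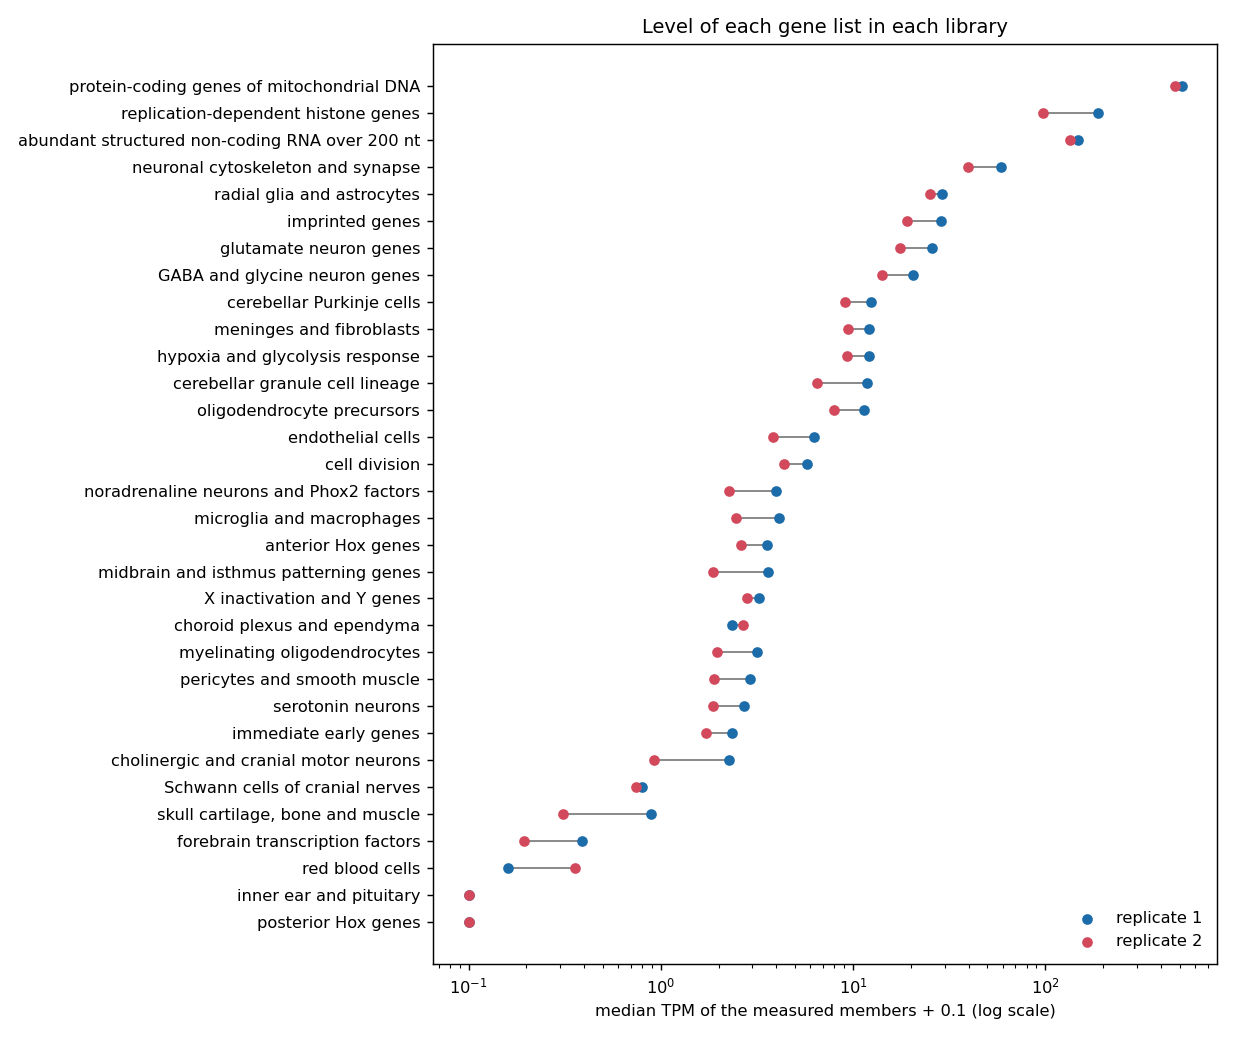
Median TPM plus 0.1 (log axis) over the measured members of each of the 32 gene lists, with a point for each library joined by a line. Mitochondrial messenger RNAs (513 and 472 TPM) have the highest medians. Histone genes (188 and 97.8) and the list of structured and long non-coding RNA (148 and 134) follow, and their order is reversed in replicate 2. Posterior Hox and inner ear and pituitary genes have a median of 0.

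Gene pairs that switch during development or mark opposite states differed in 13 of the 14 measured pairs by more than the spread between libraries. The series has 1 age, so no change over time was measured. The potassium chloride exporter gene Slc12a5 exceeded the importer gene Slc12a2 13.6-fold, with 75.5 ± 19.3 against 5.42 ± 1.13 TPM (SD, n = 2). The NMDA receptor gene Grin2b exceeded Grin2a 3.22-fold, the glycine receptor gene Glra2 exceeded Glra1 5.11-fold, and the sodium channel gene Scn3a exceeded Scn1a 3.25-fold. The vesicular glutamate transporter gene Slc17a6 exceeded Slc17a7 9.47-fold. The light neurofilament gene Nefl exceeded the heavy Nefh 15.0-fold.

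Among glial and cell cycle pairs, Gfap exceeded Nes 2.35-fold, Mbp exceeded Pdgfra 2.82-fold and Ccnd1 exceeded Ccnd2 2.24-fold. Gabra3 was at least 504-fold higher than Gabra6, and the adult globin gene Hbb-bs at least 2384-fold higher than the embryonic Hbb-y, each against a floor of 3 counts per library. The deposited interval of Gabra6 reaches 0.046 TPM in replicate 1, above its floor of 0.0199, so its ratio may be smaller. Cspg4 had 8.63 ± 2.55 TPM against 0.050 ± 0.071 for Mog (SD, n = 2). Gad1 exceeded Slc6a5, the glycine transporter gene, 2.00-fold, with a log2 ratio of 1.00 ± 0.087 that barely passed the limit of 0.999. Lin28b was not set against Mirlet7bhg, which had no match in the tables. A pair was called where both libraries had the same sign and the mean log2 ratio exceeded 3 SD and the 95th percentile of the difference between libraries of genes at that level. That limit is the difference of the same gene between libraries. How many random pairs of genes pass it was not measured, so the number called shows nothing particular to these pairs. With a pseudocount of 1 the calls for Scn3a, Ccnd1 and Gad1 were lost, with 0.01 that for Cspg4, and in replicate 1 alone those for Gfap and Gad1.

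The transcript tables gave the share of each gene's TPM held by its leading transcript for 25 fixed genes, and in 17 of them it held at least 50% in both libraries. Ptbp2 has a single transcript in the tables. For the tau gene Mapt the 10-exon Mapt-204 held 98.6 ± 0.56% (SD, n = 2), for Snrpn Snrpn-201 held 96.5 ± 1.96%, for Snap25 Snap25-201 held 95.7 ± 1.35% and for Gfap Gfap-201 held 89.4 ± 2.63%. Bin1-201 held 84.8 ± 4.96%. For Ntrk2, the receptor of BDNF, the 18-exon Ntrk2-201 with a coding sequence of 2463 nt held 59.1 ± 1.62% and the 12-exon Ntrk2-202 with 1428 nt held 40.9 ± 1.62%. Cdc42-202 held 64.2 ± 0.63%, Dclk1-201 63.6 ± 0.98%, Clta-204 64.9 ± 2.33%, Tpm1-209 67.3 ± 0.52%, Tpm3-201 61.8 ± 2.73%, Nfasc-202 59.1 ± 7.65%, Grin1-205 54.3 ± 4.11% and Fgfr1-202 51.2 ± 0.84%. The pyruvate kinase gene Pkm was shared between Pkm-202 (52.9 ± 2.68%) and Pkm-201 (47.1 ± 2.68%).

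The leading share differed by over 10 percentage points between libraries for Mbp and Nfasc, among others. Mbp-203, of the myelin basic protein gene, held 37.3% in replicate 1 and 23.9% in replicate 2, where Mbp-211 held more (26.8%). Nfasc-202 held 53.7% and 64.5%. No transcript held 50% of the TPM in both libraries for genes that include Mbp, Map2, Gria2, Ncam1, Ank3, Meg3 and Vegfa. Transcript estimates divide shared reads between forms and are less certain than gene values. Short partial transcripts weigh more in TPM than in counts, so Map2-218, of 546 nt, held 23.3% of the TPM of Map2 but 2.15% of its counts, and Vegfa-202 held 30.2% of TPM but 67.1% of counts.

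The 2 libraries differed by over 2-fold in 710 of 13996 protein-coding genes with a mean count of at least 50. Of these, 429 were higher in replicate 2 and 281 in replicate 1, where counting error alone gave 0.13 and 0.07 genes on average in 100 simulations. Spike-ins, which carry no biological difference, also spread beyond counting error. At 50 to 200 counts their SD was 1.17 against 0.226 from counting error, and coding genes had 1.21. The number over 2-fold therefore does not separate biological from technical differences. Muscle genes were prominent among those higher in replicate 1. Of the 10 with the largest ratio, Ckm (muscle creatine kinase, log2 ratio of replicate 2 over replicate 1 of −2.95), Acta1 (skeletal actin, −2.65), Myh8 (perinatal myosin, −2.22) and Ttn (titin, −2.13) encode muscle proteins. The other 6 were Gm21887 (−3.25), Xntrpc (−2.93), Snrnp35 (−2.15), 1700037C18Rik (−2.01), BC037034 (−1.73) and Pcdhb2 (−1.73). The 10 highest in replicate 2 were Fam205a4 (3.00), Ackr2 (2.24), Acad10 (2.15), Rsc1a1 (2.13), Hist1h4k (2.04), Mmp23 (1.95), Gm28036 (1.88), Carmil2 (1.73), Cep95 (1.70) and Rps29 (1.69). Of these 20 genes 7 had counts that were not whole, so part of their reads was shared with other genes. By TPM ratio the split was 156 higher in replicate 2 and 1251 in replicate 1, since the TPM of most genes was lower in replicate 2.

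Most genes agreed closely. Across the 13996 genes Pearson's r of log2 TPM was 0.968 and Spearman's rho 0.975, which describe genes and not independent replicates, and 86.8% of genes lay within 1.5-fold. The SD of the log2 ratio was 1.21 for genes with a mean count of 50 to 200, 0.504 from 200 to 1000, 0.254 from 1000 to 5000 and 0.155 above. The spike-ins, which carry no biological difference, had SDs of 1.17, 0.480, 0.246 and 0.133 over 10, 9, 9 and 11 sequences in the same ranges. Counting error gave 0.211, 0.092, 0.044 and 0.022 for the coding genes. Ratios of single genes with few counts are therefore uncertain well beyond counting error. The coefficient of variation estimated by edgeR over 17632 genes of all types was 0.372. It was 0.2775 for 15314 protein-coding genes and 0.193 for genes of all types with a mean count of at least 100. Because the spike-ins vary as much, the coefficient is not a measure of animals alone. Spike-in RNA took 0.870% of counts in replicate 1 and 0.813% in replicate 2, a mean of 0.842 ± 0.040% (SD, n = 2).

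**Figure D3:**
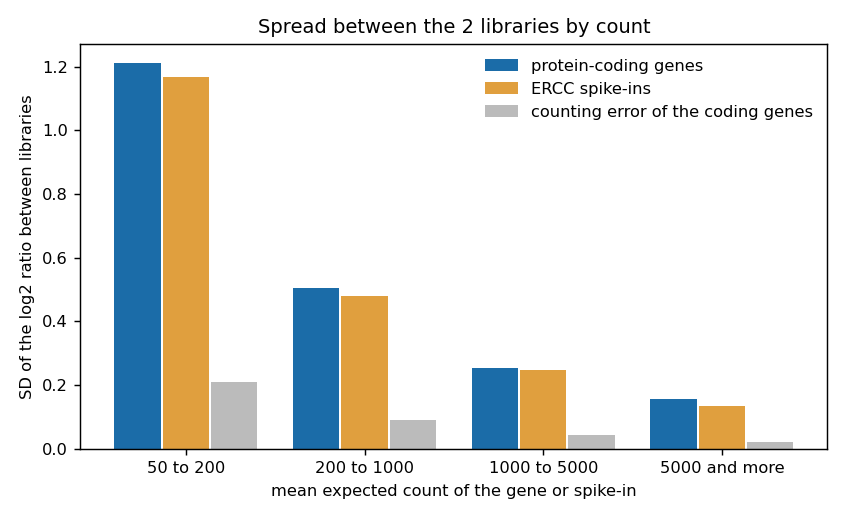
SD of the log2 ratio between the 2 libraries, by mean expected count, for protein-coding genes and ERCC spike-ins, with the counting error of the coding genes beside them. Both fall with the count, from 1.21 and 1.17 at 50 to 200 counts to 0.155 and 0.133 at 5000 counts and more.

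Between the libraries, blood, choroid plexus, myelin and cerebellar genes were higher in replicate 2, and muscle and posterior Hox genes in replicate 1. The lists were compared by the median log2 ratio of scaled counts (replicate 2 over replicate 1) and its percentile among 10000 random lists matched on mean count. Of 32 lists 13 lay outside the central 95%, 9 toward replicate 2 and 4 toward replicate 1, where about 1.6 would for lists of unrelated genes. Genes of a list can move together within a library, so this describes the 2 libraries and is not a test across animals. All 8 erythroid genes with a mean count of at least 10 were higher in replicate 2 (median 0.87, 100th percentile), among them Hba-a2 (0.26), Hbb-bs (0.32) and Hbb-bt (1.09). For choroid plexus and ependyma the median was 0.44 (99.9th), with 12 of 13 genes positive, including Ttr (0.62), Aqp1 (0.91) and Otx2 (0.72).

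Other lists toward replicate 2 had smaller medians. The myelin median was 0.35 (99.5th percentile), with Mbp at 0.48 and Cnp at 0.32. In the granule cell lineage 18 of 24 genes were positive with a median of 0.19 (99.98th), including Zic1 (0.22), Pax6 (0.40) and Atoh1 (1.03), while Meis2 (−0.27) and Cbln3 (−1.54) were negative. The Purkinje list had a median of 0.12 (99.0th) and the cell division list 0.20 (99.2nd). The non-coding RNA list holds long non-coding RNAs, such as Malat1 and Meg3, besides the structured RNAs, so its median does not describe structured RNA alone. That list (0.48, 100th), mitochondrial messenger RNA (0.15, 99.97th) and the X inactivation and Y list (0.33, 97.8th) completed those toward replicate 2. In that last list Xist was lower in replicate 2 (−0.61), Ddx3y (0.82), Eif2s3y (0.55) and Kdm5d (0.33) were higher, and Uty was at 0.00.

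Toward replicate 1, the cartilage, bone and muscle list had a median of −1.49, below all 10000 random lists. Its muscle genes accounted for this, with 6 of 7 under −1, while 1 of 6 cartilage and bone genes was, a split made after the values were seen. Mylpf had 160 counts in replicate 1 and 2 in replicate 2, and Myod1, a muscle transcription factor with 11 and 49 counts, went the other way. Posterior Hox genes had a median of −0.99 (0.11th percentile) over 7 genes, with Hoxb8 at −1.22, Hoxa6 at −1.05 and Hoxb7 at −0.99, and Hoxc6 at 1.49. The cholinergic and motor list had −0.28 (1.84th), with Prph at −0.42 and Ret at −0.27, and the histone list −0.12 (1.54th). The TPM ratio shifts coding genes by −0.51, so under it the medians of 8 of the 9 lists toward replicate 2 turned negative, and the percentiles of the Purkinje, myelin, division, mitochondrial and X inactivation lists and of the cholinergic list (4.1st) came inside the central 95%.

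The other 19 lists lay inside the central 95%. Their medians were −0.35 for forebrain (2.78th percentile), −0.31 for inner ear and pituitary, −0.23 for serotonin neurons, −0.22 for pericytes and smooth muscle (3.3rd), −0.13 for endothelial cells and −0.12 for oligodendrocyte precursors. Pan-neuronal genes had −0.09, midbrain and isthmus genes −0.09, imprinted genes −0.08, GABA and glycine genes −0.04 and anterior Hox genes −0.01. Meningeal genes had 0.02, glutamate neuron genes 0.04, radial glia and astrocyte genes 0.04 (97.2nd), immediate early genes 0.06, hypoxia genes 0.06, microglia genes 0.15, noradrenaline neuron genes 0.21 and Schwann cell genes 0.26. With a minimum mean count of 50 the forebrain list also lay outside, at −0.81 (0.05th), as it did by TPM ratio, at −0.855 (1.11th), and at that minimum all 13 above stayed outside.

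**Figure D4:**
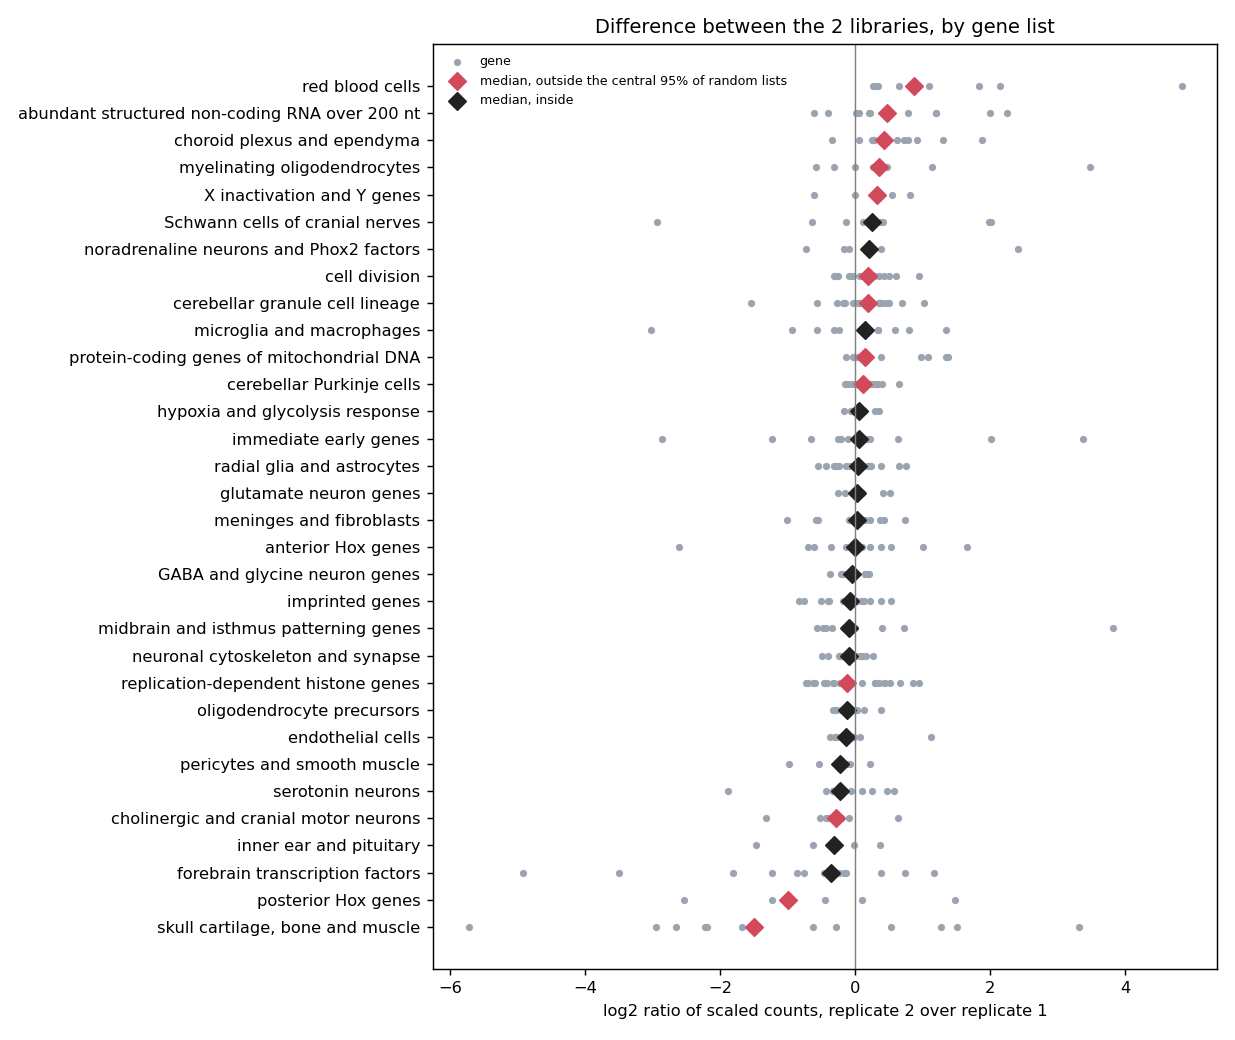
Log2 ratio of scaled counts, replicate 2 over replicate 1, for each gene with a mean count of at least 10 (grey points) and the median of each list (diamonds, red where it lies outside the central 95% of 10000 matched random lists). The red blood cell list is highest at 0.87, and the cartilage, bone and muscle list lowest at −1.49.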

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

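The libraries hold signal outside the sequences compared. PhiX, a phage whose DNA is commonly added to sequencing runs as a control, had 222726 counts in replicate 1 and 215696 in replicate 2, or 0.345 ± 0.092% of counts (SD, n = 2). It stands out because no comparison used it and a count of 0 would allow 3. Mouse genes with no symbol in the newer annotation had 71361 and 115755 counts. They are 884 genes, of which 157 had counts in both libraries and 3 held 24.1% of these counts.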

How the results depend on the processing

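The alternatives rescaled TPM for detection and for the Hox difference, at least 10 counts for detection and spike-in scaling of list shifts were chosen after seeing the data. The number of detected coding genes was 6952 at a TPM of at least 5, and within 1.5 times of 11725 in the 7 other settings, with 11908 to 12459 when each library stood alone. Lists at or over the upper limit of the level percentile were 10, but 6 against a background of genes with a mean TPM of at least 0.1, where granule (97.3), Purkinje (95.04), meningeal (92.2) and hypoxia (90.7) genes fell below. Against that background 25 of 29 percentiles moved, all of them down. That direction was fixed in advance, because low genes left the random pool but not the lists. With replicate 2 alone 12 moved and with replicate 1 alone 9, among them erythroid genes (9.38 to 15.4) and cartilage, bone and muscle genes (20.5 to 11.1) in replicate 2 and inner ear and pituitary genes (1.26 to 2.22) in replicate 1. The Hox minus forebrain difference of 3.47 was 4.06 with a pseudocount of 0.01, 1.74 with 1, 2.60 with means for medians and 3.97 with TPM rescaled to coding genes, and 3.20 to 3.74 for single libraries. Pairs past the limit were 13, 12 with a pseudocount of 0.01, 10 with 1 and 11 to 13 for single libraries. Genes over 2-fold were 710, 2304 with no minimum count, 193 at a mean count of at least 200 and 1407 by TPM ratio, while 521 higher and 237 lower in replicate 2 came from spike-in scaling. The coefficient of variation of 0.372 was 0.2775 for protein-coding genes only, 0.193 at a mean count of at least 100 and 0.192 as DESeq2's median. Lists outside the central 95% were 13, and 8 by TPM ratio, where forebrain joined them at −0.855. There the medians toward replicate 2 turned to −0.30 for granule, −0.43 for Purkinje, −0.22 for myelin, −0.021 for choroid plexus and −0.37 for cell division genes. They turned to −0.16 for structured and long non-coding RNA, −0.43 for mitochondrial and −0.41 for X inactivation and Y genes. All lay above the shift of −0.51 that this ratio gives a typical coding gene. Other changes were not traced and the cause was not tested. Spike-in share ran from 0.813% to 0.870% between libraries, and 17 transcripts led in each alone. Top transcript shares moved by more than their spread in 16 of 25 genes when counts replaced TPM. Depth and effective length set the floor of genes with 0 counts, in replicate 1 0.018 TPM for Hemgn and 0.440 for Bglap. No paired analysis was possible because the series has 1 group.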

Other observations

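The messenger RNAs of mitochondrial DNA, which are cut from shared precursors, did not move together between the libraries. The log2 ratio of replicate 2 over replicate 1 was 0.09 for mt-Co1, −0.03 for mt-Co3, 0.06 for mt-Nd1 and −0.13 for mt-Nd2, but 0.98 for mt-Co2, 1.08 for mt-Atp6, 1.35 for mt-Nd4l and 1.37 for mt-Atp8. The mitochondrial ribosomal RNAs mt-Rnr1 (955 nt) and mt-Rnr2 (1582 nt) had 0.33 and −0.23. Transcript length was not compared, so recovery that differs with length is not excluded as the source. The neighbouring imprinted non-coding genes Meg3, Rian and Mirg had ratios of 0.54, 0.02 and 0.78. Rps29, a ribosomal protein gene among the 10 highest in replicate 2, lies 109 nt from Rn7s1 on chromosome 12, on the other strand. Dlx2, a forebrain factor, had 48 counts in replicate 1 and 0 in replicate 2.

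The medians of the gene lists were planned, and the other tests below were chosen after the patterns were seen. Of these, the bounds for short RNA recovery on spike-ins and coding genes and for the second muscle list were written before their own results were seen, and those for effective length, Rmrp, counting error, scaling and sex after. The bound for scaling of Xist and the Y genes replaced an earlier one on the sign of each Y gene, which Uty near 0 could not decide. No biological explanation was tested between groups, since the series has 1 group.

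The 5 structured RNAs held 61.7% and 74.0% of TPM, and a candidate explanation is that effective lengths near 0 inflate them. Dividing the same counts by full length lowered the share to 8.02% and 24.4%, which left part of it in replicate 2. A fall was fixed in advance, because full length exceeds effective length most for such short RNA, so only its size is informative. Their share of counts was 1.17% and 4.34%, so the share depends strongly on the length used. The higher counts of Rn7sk (log2 ratio 2.25), Rn7s1 and Rn7s2 (1.20) and Rpph1 (2.01) in replicate 2 may come from its shorter fragments recovering short RNA better. Coding genes of 250 to 350 nt had a median of 0.513 but were 5 genes with an SD of 0.889, and spike-ins of 505 to 600 nt lay at −0.208 against those over 1000 nt, none of them as short as the RNAs, so this stays open. Rmrp, the shortest of the 5, had −0.405, opposite in sign but within that SD, so this stays open for it too.

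Muscle genes were higher in replicate 1, and skeletal muscle left on the dissected tissue is a candidate source. In a second list of 30 muscle genes, none of them in another list, 40% of the 25 with a mean count of at least 10 had a log2 ratio under −1, against 15.7% in matched random lists, and the median was −0.548 (0.29th percentile). This lay between the bounds set for the test of over 50% and under 20%, and how many of these genes hindbrain cells express was not measured, so it stays open. Atp2a1 had 274 counts in replicate 1 and 30 in replicate 2, Tnnc2 108 and 1 and Myl1 111 and 16, but Ryr1 had 886 and 1470 and Pygm 573 and 932. The tables argue against counting error alone, which gave a median as low as that of the first list in 0 of 100 draws. The spike-ins spread beyond counting error at every count, and the draws leave that spread out. Other technical differences between the libraries are therefore not excluded.

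Xist was lower and 3 of 4 Y genes were higher in replicate 2, and a larger share of males in that pool is a candidate explanation. The test asked for all 4 Y genes over 0.3 in its favour and for any Y gene under 0 against it. Uty, at −0.001, meets the second bound as written. That value lies far inside the SD of 0.504 of genes with 200 to 1000 counts, so the explanation stays open. The summed counts of the 4 Y genes had a log2 ratio of 0.43, and of 1160 genes with a mean count of at least 10000, 2, Xist among them, had a ratio as low as that of Xist. Other X-linked coding genes differed from autosomal genes by −0.02 in the median over 493 genes. The tables argue against scaling between libraries, since it moves all genes alike and the summed Y genes and Xist lay 1.036 apart, beyond the upper limit of 0.506 from 10000 sets of autosomal genes matched on count.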
